A study of Rattus norvegicus with 12 samples.

How the data were processed

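RNA was sequenced from rat kidney in 12 samples, 4 sham, 4 with cardiopulmonary bypass (CPB) and 4 with bypass and nitrite (CPB+Nitrite). Groups and replicate numbers came from the sample labels. Per the labels' protocols, total RNA was extracted with QIAzol, treated with TURBO DNA-free DNase and made into strand-specific libraries with a NEBNext Ultra II Directional kit. Per the submitters' processing notes, which give no order or options, the tools included bcl2fastq 2.19, cutadapt 1.18, Salmon 1.2.1 and R 3.5.1 with the genome build mRatBN7.2.

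The deposited count table held the authors' estimated counts per Ensembl gene, not normalised. Of its non-zero values 33.1% were not whole numbers (tolerance 1e-06), and the 7 largest values were rounded to 3 digits in the file. How transcripts were summed to genes is not stated. The second deposited table held a scaled signal, in which the authors had multiplied the counts of each library by 1 factor (largest departure from a single factor 0.0033 of its value, in genes of 100 reads or more). That table supplied gene symbols and coordinates, and its factors were used only as an alternative scaling. Symbols were found for 18208 of the 20455 genes with reads. Genes with a near-identical copy, such as Hspa1b and Hspa1a, share reads in a way the tables do not resolve.

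Library totals ran from 16.8 to 25.8 M reads (M, mega). Counts were rounded and genes kept by edgeR's filterByExpr with a minimum count of 10, which left 14664 genes with 99.95% of the reads. Libraries were scaled with edgeR's TMM factors (0.887 to 1.11), and counts-per-million (CPM) use these. The spread between replicates, as the biological coefficient of variation, was 0.317. The precision of each difference was set by 4 replicates and 9 residual degrees of freedom more than by depth.

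All 3 comparisons came from 1 fit of the 12 libraries with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, no covariates). Adjusted p-values used the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05, and each test was two-sided. Standard errors of log2 changes came from the quasi-likelihood F statistic. Gene lists were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the 37 lists with at least 3 tested members. Beside it stand camera with a correlation estimated from the data and limma's fry test. List level per library was the mean log2 CPM (prior count 2) over members, relative to the sham mean. The gene lists, comparisons, tests, thresholds and most alternatives were fixed before the data were examined.

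Named genes followed a rule. It took the 8 largest positive and 8 largest negative log2 changes among genes past the threshold whose groups did not overlap and whose mean was at least 2 CPM, and up to 4 members with the smallest p past the threshold per list. Where fewer than 6 genes passed it took the 10 with the smallest p. It also took 13 genes in every comparison: Havcr1, Lcn2, Hmox1, Nos2, Nos3, Il6, Il1b, Tnf, Ccl2, Cxcl1, Icam1, Slc34a1 and Umod. Of the genes the rule allows, a part is named.

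The share of the bypass change remaining with nitrite was the median over genes of the log2 difference of CPB+Nitrite from sham divided by that of CPB from sham. Genes were called on 2 sham and 2 CPB libraries and measured on the other libraries, over all 36 splits. Overlaps of calls between comparisons that share a group were also counted with that group's libraries split 2 and 2. Overlaps expected of independent calls and of simulated unchanged groups were computed and are not used, since the comparisons share libraries and the unchanged groups gave an overlap of 0.

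The test was checked on simulated counts drawn from the means of the real genes with 200 changed genes. For CPB versus sham it recovered 4.48% of genes changed 1.5-fold, 35.8% of those changed 2-fold and 93.9% of those changed 4-fold, with 3.3% false among its calls. For CPB+Nitrite versus CPB the shares were 2.99%, 31.3% and 87.9% (4.7% false), and for CPB+Nitrite versus sham 2.99%, 22.4% and 90.9% (2.5% false). The median correlation of a library with its own group was 0.918 to 0.947 in CPB+Nitrite and 0.973 to 0.98 in CPB. The simulated counts were drawn with the same spread per gene in every group, so they did not hold this wider spread. With the real counts CPB+Nitrite versus CPB gave 0 calls, although Ifit2 had a log2 change of -2.26 and Cxcl11 of -2.54. The simulated shares are therefore not shown to hold for the comparisons with CPB+Nitrite. Nor are they for CPB versus sham, where the simulation called 92 genes and the real counts 6332. More calls let a larger unadjusted p pass the adjusted threshold, so recovery depends on how many genes change.

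Alternatives were median-of-ratios (RLE) factors, total counts alone, no filter, a stricter filter at a mean of 2 CPM, the replicate number as a block, DESeq2 1.42.0, limma voom with sample weights, edgeR's glmTreat at 1.2-fold, a fit of only the 8 libraries compared, and each library left out in turn. The factors of the deposited scaled table, a threshold of 0.1 and leaving out libraries of the third group were chosen after seeing the data. Gene-set enrichment over the biological process terms of the deposited annotation, also chosen after seeing the data, used terms of 15 to 500 tested genes with the annotated tested genes as background.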

Results

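The data set held RNA sequencing of rat kidney from 12 libraries in 3 groups of 4. Sham animals served as controls, the CPB group underwent cardiopulmonary bypass (circulation through a heart-lung machine), and the CPB+Nitrite group underwent bypass with nitrite, an anion that can be reduced to nitric oxide. The title of the series frames nitrite as a treatment against kidney injury after cardiac surgery. The labels give no dose, duration or time of sampling. Nothing in them states that the replicates are separate animals, so every p-value below measures only the spread between these samples. Values were estimated read counts for 30208 Ensembl genes, of which 20455 had at least 1 read in any library and 14664 were tested. The sham libraries held 25.4, 22.3, 24.2 and 19.2 M reads. The CPB libraries held 25.8, 19.1, 19.8 and 16.8 M, and the CPB+Nitrite libraries 24.8, 25.4, 20 and 22.8 M. The first principal component carried 52.4% of the variance and set all 4 sham libraries (-73.9 to -37.4) apart from all 4 CPB libraries (46.8 to 76.0). CPB+Nitrite libraries 1 and 4 lay toward the CPB side at 42.4 and 27.3, and libraries 2 and 3 on the sham side at -49.8 and -33.3. On the second component (16.2% of the variance) CPB+Nitrite 2 lay apart at -91.9, with all other libraries at -36.4 to 27.6. The median correlation of a library with its own group was 0.966 to 0.977 in sham, 0.973 to 0.980 in CPB and 0.918 to 0.947 in CPB+Nitrite, lowest in CPB+Nitrite 2.

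**Figure D1:**
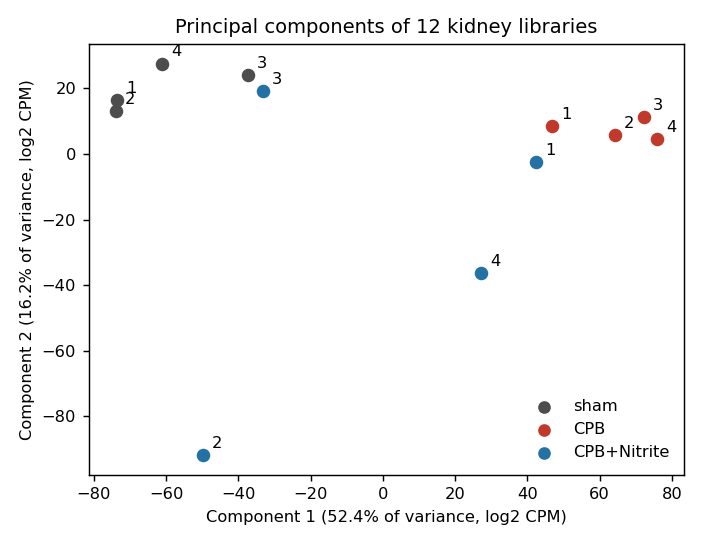
First and second principal components (log2 CPM) of the 12 libraries, one point per library, coloured by group with the replicate number beside it. The 4 CPB libraries lie at 46.8 to 76.0 on the first component, the 4 sham libraries at -73.9 to -37.4, and the 4 CPB+Nitrite libraries at -49.8 to 42.4. On the second component CPB+Nitrite 2 lies at -91.9 and all other libraries at -36.4 to 27.6.

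CPB versus sham addressed what bypass does to the transcripts of the kidney. Most of the tubular injury markers, interferon-stimulated genes, chemokines, acute-phase genes and stress-response genes tested were higher after bypass, and part of the genes of fatty acid oxidation, of the citric acid cycle and of tubule segments were lower. Havcr1, which encodes kidney injury molecule 1 of damaged proximal tubules, rose from 10.7 ± 10.6 to 773 ± 236 counts-per-million (CPM; mean ± SD, n = 4 per group). Ifit2, an antiviral protein induced by interferon, rose from 12.2 ± 5.21 to 624 ± 206 CPM, and Hmox1, which degrades haem, from 8.42 ± 2.45 to 541 ± 108. Slc34a1, the phosphate transporter of the proximal tubule, fell from 1594 ± 237 to 925 ± 211. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6332 of 14664 genes passed (43.2%), 3184 higher and 3148 lower, and 1490 of the higher and 1694 of the lower genes differed by more than 2-fold.

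The injury markers were tested in 25 genes, of which 17 rose and 8 did not pass (19 rose adjusted over the list alone). Havcr1 (ENSRNOG00000007243, chromosome 10, 31119088 to 31151698, build mRatBN7.2) changed by 6.18 on the log2 scale with a standard error of 1.10 (adjusted p = 0.00187). Timp1, an inhibitor of matrix proteases, rose by 4.23, the fibrinogen chain gene Fgg by 7.31 and Lcn2, which binds bacterial siderophores, by 3.37 (by 5.53 without sham 3). Among 25 cytokines and chemokines 17 rose (18 adjusted over the list alone), with log2 changes of 5.62 for Il6, 5.97 for Cxcl2, 6.66 for the T cell chemokine Cxcl11, 4.51 for the monocyte chemoattractant Ccl2 and 4.36 for Cxcl1. Il1b rose by 1.29, and this call was lost without sham 1 (1.2) or sham 4 (1.17). Tnf was at 0.997 ± 0.496 CPM in sham and 2.13 ± 1.26 in CPB (adjusted p = 0.247). Of 21 targets and regulators of NF-kappaB 18 rose (18 adjusted over the list alone), Nfkb1 by 2.04 and the adhesion molecule Icam1 by 2.39. Of 18 genes of the acute-phase response 15 rose (15 adjusted over the list alone), the copper-carrying oxidase Cp by 1.64. Each of these lists passed limma's camera test against all other genes (adjusted p from 6.93e-08 to 2.88e-07), and none passed with a correlation estimated from the data (adjusted p = 0.301 with an estimated correlation, for each of the 4 lists).

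Interferon-stimulated genes were the list with the largest median, 3.88 on the log2 scale, among the 37 lists tested. All 25 tested members rose (25 adjusted over the list alone; camera adjusted p = 4.54e-15, adjusted p = 0.301 with an estimated correlation). Ifit2 (ENSRNOG00000036604, chromosome 1, 232102570 to 232108635) rose by 5.68 with a standard error of 0.75 and the transcription factor Irf7 by 4.29 with a standard error of 0.58. Cell-stress lists followed the same direction. In the unfolded-protein and integrated stress response 19 of 24 genes rose (20 adjusted over the list alone; median 1.15, camera adjusted p = 2.02e-07, adjusted p = 0.301 with an estimated correlation), among them the transcription factor Atf4 by 2.15 and Ppp1r15a by 3.78. In the heat-shock response 13 of 20 rose (14 adjusted over the list alone; camera adjusted p = 0.000158, adjusted p = 0.436 with an estimated correlation). The mean level of that list was 0.259 log2 units above the sham mean in CPB 1 and 1.51 to 2.28 in CPB 2 to 4. Hspa1b was at 251 ± 72.8 CPM in sham and 13070 ± 12900 in CPB and shares reads with its near-identical copy Hspa1a, so its value is uncertain. Of 26 immediate-early genes 14 rose (15 adjusted over the list alone; camera adjusted p = 1.74e-05, adjusted p = 0.343 with an estimated correlation), Jund by 1.41. Of 6 metallothioneins and zinc-response genes 5 rose (5 adjusted over the list alone; camera adjusted p = 0.00865, adjusted p = 0.343 with an estimated correlation), Mt2A by 2.05, a gene with a close copy in Mt1.

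Genes of cell death and of cell-cycle arrest were mostly higher as well. Among 26 genes of apoptosis, necroptosis, pyroptosis and ferroptosis 19 rose and 2 fell (20 and 2 adjusted over the list alone; camera adjusted p = 2.09e-06, adjusted p = 0.301 with an estimated correlation), including Mlkl, the executor of necroptosis, by 2.63 and the inflammatory caspase Casp4 by 3.25. Of 20 p53 targets 12 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.00298, adjusted p = 0.301 with an estimated correlation). The pro-apoptotic Bbc3 rose by 1.94 and the stress-induced Sesn1 fell by 0.78. Without sham 1 the p53 counts were 8 and 1. Of 24 complement and coagulation genes 12 rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.00585, adjusted p = 0.301 with an estimated correlation), complement factor Cfb by 3.51. Targets of hypoxia-inducible factor split, with 9 of 23 higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.0089, adjusted p = 0.343 with an estimated correlation). The glycolytic regulator Pfkfb3 rose by 2.94 and its relative Pfkfb4 fell by 3, and without sham 4 the hypoxia counts were 5 and 2.

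Part of the metabolic genes were lower. In fatty acid oxidation 18 of 29 genes fell and 1 rose (19 and 1 adjusted over the list alone; median -0.64, camera adjusted p = 9.21e-06, adjusted p = 0.301 with an estimated correlation), with Hadh down by 0.88 and Ehhadh by 1.30 on the log2 scale. In the citric acid cycle and gluconeogenesis 10 of 19 fell and none rose (11 fell adjusted over the list alone; camera adjusted p = 0.000102, adjusted p = 0.301 with an estimated correlation). Pck1, a gluconeogenic enzyme, fell by 3.81 and the mitochondrial enzyme Idh2 by 0.90, and the mitochondrial regulator Ppargc1a fell by 1.55. Of 27 nuclear genes of oxidative phosphorylation 8 fell (4 adjusted over the list alone; median -0.34, camera adjusted p = 0.00116, adjusted p = 0.475 with an estimated correlation), among them Ndufs3 by 0.76. That count was 5, 3 and 4 without sham 1, 2 and 3, 2, 4 and 3 without CPB 2, 3 and 4, and 13 without CPB+Nitrite 4. Cell-cycle genes also fell, 13 of 25 with 1 higher (13 and 1 adjusted over the list alone; camera adjusted p = 0.00293, adjusted p = 0.343 with an estimated correlation), where the thymidylate synthase gene Tyms fell by 2.30 and Top2a fell by 1.74. Without sham 3 or without CPB 3 the count was 8 lower and 1 higher.

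Some markers of nephron segments were lower, while the others did not pass or, in 1 case, rose. Of 27 proximal tubule markers 10 fell (10 adjusted over the list alone; camera adjusted p = 0.00298, adjusted p = 0.301 with an estimated correlation), including the organic anion transporter Slc22a6 by 1.06 and Slc34a1 (ENSRNOG00000015262, chromosome 17, 9218876 to 9233852) by 0.78 with a standard error of 0.19 (adjusted p = 0.00634). Of 21 markers of the loop of Henle and distal tubule 8 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.347 with an estimated correlation), the calcium-sensing receptor Casr by 3.90. Among the genes with the largest falls, the potassium channel Kcnj10 of the distal tubule fell by 3.83 and the glucose transporter Slc2a4 by 3.95. Umod, the uromodulin gene of the thick ascending limb, was at 5969 ± 884 CPM in sham and 4967 ± 1020 in CPB (adjusted p = 0.725). Of 22 collecting duct markers 10 fell (10 adjusted over the list alone; camera adjusted p = 0.0068, adjusted p = 0.343 with an estimated correlation), the proton pump subunit Atp6v1b1 by 1.80 and the ammonia channel Rhcg by 1.2. Markers of fibroblasts, pericytes and smooth muscle fell in 10 of 17 genes (10 adjusted over the list alone; camera adjusted p = 0.00404, adjusted p = 0.347 with an estimated correlation), Notch3 by 1.38 and smooth muscle actin Acta2 by 2.61, where Acta2 fell by 1.39 without sham 1. That count was 6 without sham 1, CPB 1, CPB 2 or CPB 3, and 8 of the 17 genes are also members of another list. Adipocyte markers fell in 6 of 12 genes (9 adjusted over the list alone; camera adjusted p = 0.0312, adjusted p = 0.475 with an estimated correlation), and in 2 without sham 1, CPB 2 or CPB 3 and 3 without CPB 4. The adipocyte and urothelial lists were at 2.05 and 2.67 log2 units above the sham mean in sham 1, against -1.53 to 0.653 and -2.81 to 0.781 in sham 2 to 4.

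Leukocyte markers changed in both directions. Of 14 neutrophil markers 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0312, adjusted p = 0.301 with an estimated correlation), S100a9 by 1.78. Of 12 markers of T, B and natural killer cells 4 rose (4 adjusted over the list alone; camera adjusted p = 0.0262, adjusted p = 0.301 with an estimated correlation), the granzyme Gzmb by 4.05. In the macrophage list the lipopolysaccharide co-receptor Cd14 rose by 1.97 while the growth factor receptor Csf1r fell by 2.62, and the list as a whole did not pass (camera adjusted p = 0.659). Genes of nitric oxide signalling and nitrite handling also moved apart. The inducible synthase Nos2 rose by 4.81, the sulfite oxidase Suox fell by 1.37, and the endothelial synthase Nos3 was at 10.9 ± 2.31 CPM in sham and 11.1 ± 2.74 in CPB (camera adjusted p of the list 0.624). In the antioxidant list Hmox1 (ENSRNOG00000014117, chromosome 19, 13467244 to 13474079) rose by 6 with a standard error of 0.80 (adjusted p = 0.000968) and Osgin1 fell by 1.59, and the list did not pass (camera adjusted p = 0.235). Camera adjusted p was 0.164 for leukocyte adhesion genes, 0.376 for glucocorticoid-responsive genes, 0.659 for clock genes, 0.624 for renin-angiotensin and vasoactive genes, 0.96 for matrix genes, 0.484 for podocyte markers, 0.779 for endothelial markers, 0.235 for erythrocyte genes, 0.128 for adrenal markers and 0.542 for urothelial markers.

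**Figure D2:**
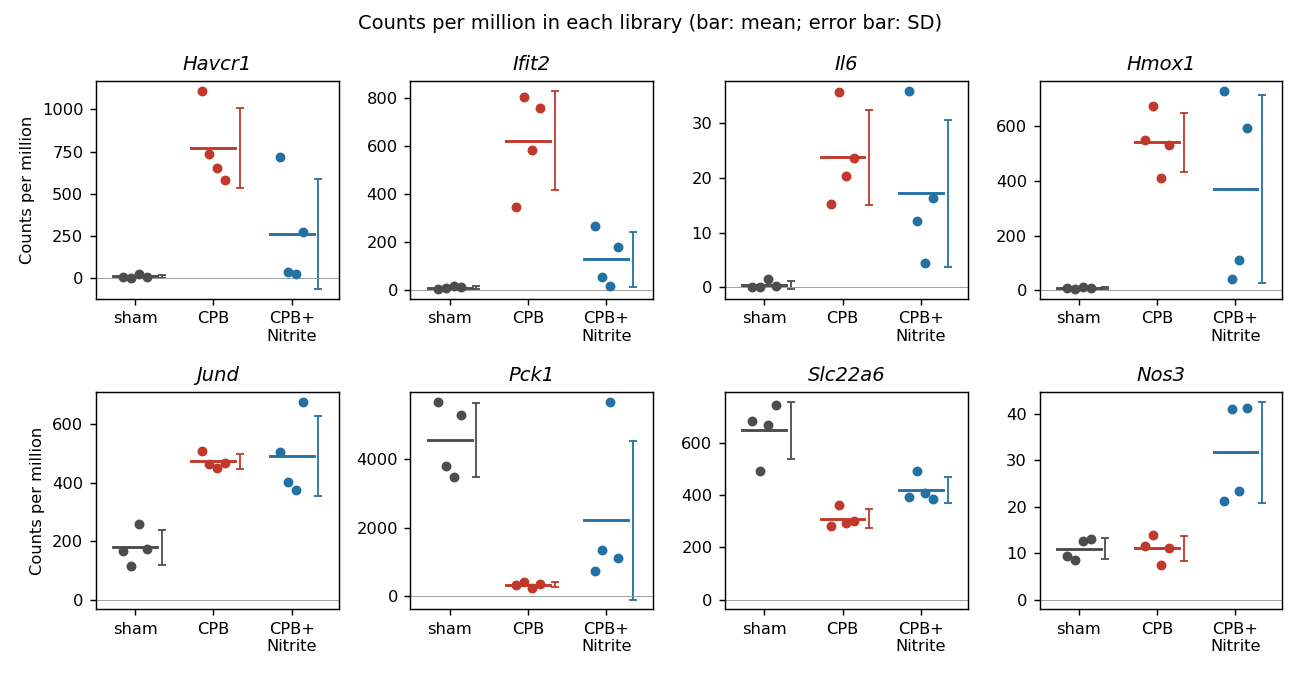
CPM of 8 genes in each of the 12 libraries, with the mean (bar) and SD (error bar) of each group of 4. Havcr1, Ifit2, Il6 and Hmox1 lie near the axis in sham and higher in CPB, Pck1 and Slc22a6 are lower in CPB than in sham, and Nos3 is at 31.7 ± 11 CPM in CPB+Nitrite against 11.1 ± 2.74 in CPB.

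In this comparison 24 of 37 lists passed camera, 15 higher and 9 lower, and 0 passed with an estimated correlation (25 passed limma's fry test, which asks only whether a list moves one way on balance). Scaling by total counts moved the median log2 change of all genes from -0.05 to -0.24 and the share of calls that were higher from 50.3% to 34.9%.

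CPB+Nitrite versus CPB addressed what nitrite changed in animals on bypass. The interferon-stimulated genes stood lower with nitrite, with the median of 25 members at -1.77 on the log2 scale and all 25 negative, and the stress-response and NF-kappaB lists stood lower by less. Podocyte, endothelial, mesenchymal, collecting duct and matrix lists stood higher, and the lists with the largest medians, urothelial and adipocyte markers, did not pass. None of the 37 lists passed with an estimated correlation (adjusted p = 0.408 to 0.575 for those past camera), and 1 passed fry. By edgeR 0 genes passed with all libraries (4315 with an unadjusted p under 0.05), while DESeq2 called 2235 and limma voom 1. Cxcl11 was at 1577 ± 796 CPM in CPB and 272 ± 355 in CPB+Nitrite (n = 4 per group), Ifit2 at 624 ± 206 and 130 ± 115, and Nos3 at 11.1 ± 2.74 and 31.7 ± 11.

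Of 14664 genes edgeR called 0 and limma voom with sample weights 1, and of the 15212 genes it tested DESeq2 called 2235 (1347 higher, 888 lower). By edgeR 4315 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0556. The count of 0 rested on single libraries: without CPB+Nitrite 1 edgeR called 2836 genes (1661 higher, 1175 lower), and without CPB 1 it called 4. Of the 35 genes followed in this comparison, 21 passed by DESeq2 and 22 without CPB+Nitrite 1. In all, 1863 genes (12.7%) did not overlap between the groups, where chance gives 2.86% on average over all arrangements of the libraries. Genes that move together let the share of a single arrangement lie far from that average. It was not computed for the other arrangements, so the excess is untested.

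Nos3 (ENSRNOG00000009348, chromosome 4, 10793834 to 10814166) had a log2 change of 1.52 with a standard error of 0.27, higher in 4 of 4 libraries than in any CPB library, at an adjusted p of 0.0556. Endothelial markers were positive in 19 of 20 genes here (mean log2 change 1.37), so more endothelium in the samples was not separated from a change in Nos3 itself. The genes with the smallest p, Nos3 not among them, included the fatty acid elongase Elovl6 (ENSRNOG00000048949, chromosome 2, 218063804 to 218171186) at 1.53 with a standard error of 0.23, the regulator of G protein signalling Rgs2 at 1.73, the matrix protein Thbs2 at 2.06, the glycine decarboxylase Gldc at 1.16, Zfp354a at 1.46 and Pacsin1 at 1.68. The lysosomal mannosidase Manba had a log2 change of -0.88 with a standard error of 0.13. Each of these had an adjusted p of 0.0556. Nos2 was at 27.4 ± 9.68 CPM in CPB and 8.37 ± 4.34 in CPB+Nitrite (log2 change -1.71, adjusted p = 0.0655). Havcr1 was at 773 ± 236 and 263 ± 326, with 721, 35.5, 22.6 and 275 CPM in CPB+Nitrite 1 to 4. Hmox1 was at 541 ± 108 and 369 ± 344, Il6 at 23.7 ± 8.66 and 17.2 ± 13.4, Ccl2 at 47.4 ± 13.2 and 34.0 ± 25.5, and Cxcl1 at 63.3 ± 19.0 and 53.3 ± 43.6. Lcn2 was at 26.1 ± 8.16 and 14.6 ± 9.31, Icam1 at 210 ± 78.8 and 135 ± 64.5, Tnf at 2.13 ± 1.26 and 4.63 ± 4.36, and Il1b at 12.4 ± 0.568 and 12.5 ± 8.19. Slc34a1 was at 925 ± 211 and 1045 ± 89.7 and Umod at 4967 ± 1020 and 3724 ± 2570. The gluconeogenic Pck1 had a log2 change of 2.77 and the glucose transporter Slc2a4 of 2.12 (adjusted p of 0.0556 and 0.0556), and without CPB+Nitrite 3 these were 1.70 and 1.35.

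Of the 37 lists, 15 passed camera, 8 lower and 7 higher, while 0 passed with an estimated correlation and 1 passed fry. The interferon list was lower (camera adjusted p = 2e-14, adjusted p = 0.52 with an estimated correlation), with 0 members past the threshold over all genes and 22 lower adjusted over the list alone. Its mean level above sham was 3.57 to 4.53 log2 units in the CPB libraries and 3.5, 1.62, 0.50 and 3.06 in CPB+Nitrite 1 to 4. Without CPB+Nitrite 1, 173 of 726 list members passed, among them 19 of 25 interferon, 14 of 26 cell-death, 10 of 24 unfolded-protein, 3 of 20 heat-shock and 0 of 27 oxidative phosphorylation genes. Atf4 (-0.65), Mlkl (-1.02) and Casp4 (-1.41) belong to lists that were lower in this comparison. The unfolded-protein list had a median of -0.67 and 12 genes lower adjusted over the list alone (camera adjusted p = 2.4e-07, adjusted p = 0.52 with an estimated correlation), and the cell-death list -0.61 and 9 genes (camera adjusted p = 8.37e-05, adjusted p = 0.52 with an estimated correlation; median -0.40 without CPB+Nitrite 2). NF-kappaB targets (-0.56), cytokines (-0.61) and heat-shock genes (-0.57) had 0, 0 and 2 genes lower adjusted over the list alone, at a camera adjusted p of 8.37e-05, 0.000375 and 0.000375 (adjusted p = 0.545 with an estimated correlation, for each). Injury markers (-0.28) and acute-phase genes (-0.42) had 0 such genes (camera adjusted p of 0.0206 and 0.0273, adjusted p = 0.575 with an estimated correlation, for each). Single libraries moved these medians. The injury median was -0.55, -0.15 and -0.63 without CPB+Nitrite 1, 2 and 4, the acute-phase median -0.74 and -0.24 without CPB+Nitrite 1 and 2 and -0.26 without CPB 3. The heat-shock median was -0.38, -0.33 and -1.48 without CPB+Nitrite 1, 3 and 4 and -0.34 without CPB 4, and the cytokine median -0.32 without CPB 2.

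Of the 7 lists that were higher, 4 held markers of podocytes, endothelium, stroma and collecting duct. Podocyte markers had a median of 0.75, positive in 15 of 15 genes, 8 of them past the threshold adjusted over the list alone (camera adjusted p = 1.27e-05, adjusted p = 0.52 with an estimated correlation). Markers of fibroblasts, pericytes and smooth muscle had a median of 1.37 and 7 such genes (camera adjusted p = 1.27e-05, adjusted p = 0.52 with an estimated correlation), with Acta2 at 2.31 and Notch3 at 1.64. Collecting duct markers had a median of 0.60 and 10 such genes (camera adjusted p = 0.00045, adjusted p = 0.52 with an estimated correlation). Endothelial markers had a median of 0.84 and 10 such genes (camera adjusted p = 2.91e-05, adjusted p = 0.545 with an estimated correlation). In CPB+Nitrite 2 the endothelial list was 1.94 log2 units above the sham mean, against -0.18 to 0.53 in the other 3 libraries of that group, and without CPB+Nitrite 2 the endothelial median was 0.43. Matrix genes had a median of 0.90 (0.57 without CPB+Nitrite 2) and 6 such genes (camera adjusted p = 0.00669, adjusted p = 0.545 with an estimated correlation). Genes of fatty acid oxidation had a median of 0.41 and 0 such genes (camera adjusted p = 0.00274, adjusted p = 0.545 with an estimated correlation). Renin-angiotensin and vasoactive genes had a median of 0.79 and 5 such genes (camera adjusted p = 0.0107, adjusted p = 0.408 with an estimated correlation), and this was the 1 list that passed fry (adjusted p = 0.0168). The immediate-early list, higher after bypass, did not pass here (median 0.45, and 0.05 without CPB+Nitrite 4; camera adjusted p = 0.179), nor did nitric oxide genes (median 0.36, and 0.21 without CPB+Nitrite 2; camera adjusted p = 0.155). Antioxidant genes did not pass either (median -0.15, and -0.04 without CPB+Nitrite 4, -0.09 without CPB 1 and -0.10 without CPB 3; camera adjusted p = 0.342). Urothelial markers had a median of 3.19, positive in 9 of 10 genes (1.4 without CPB+Nitrite 1), and adipocyte markers a median of 2.03, positive in 11 of 12 (1.21 without CPB+Nitrite 2), at a camera adjusted p of 0.0571 each. In all 22 lists did not pass, at a camera adjusted p from 0.0571 to 0.899. Among these, the median, mean and camera direction differed in sign for complement and coagulation, hypoxia, p53, clock and erythrocyte genes; in every list that passed in any comparison they had the same sign.

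**Figure D3:**
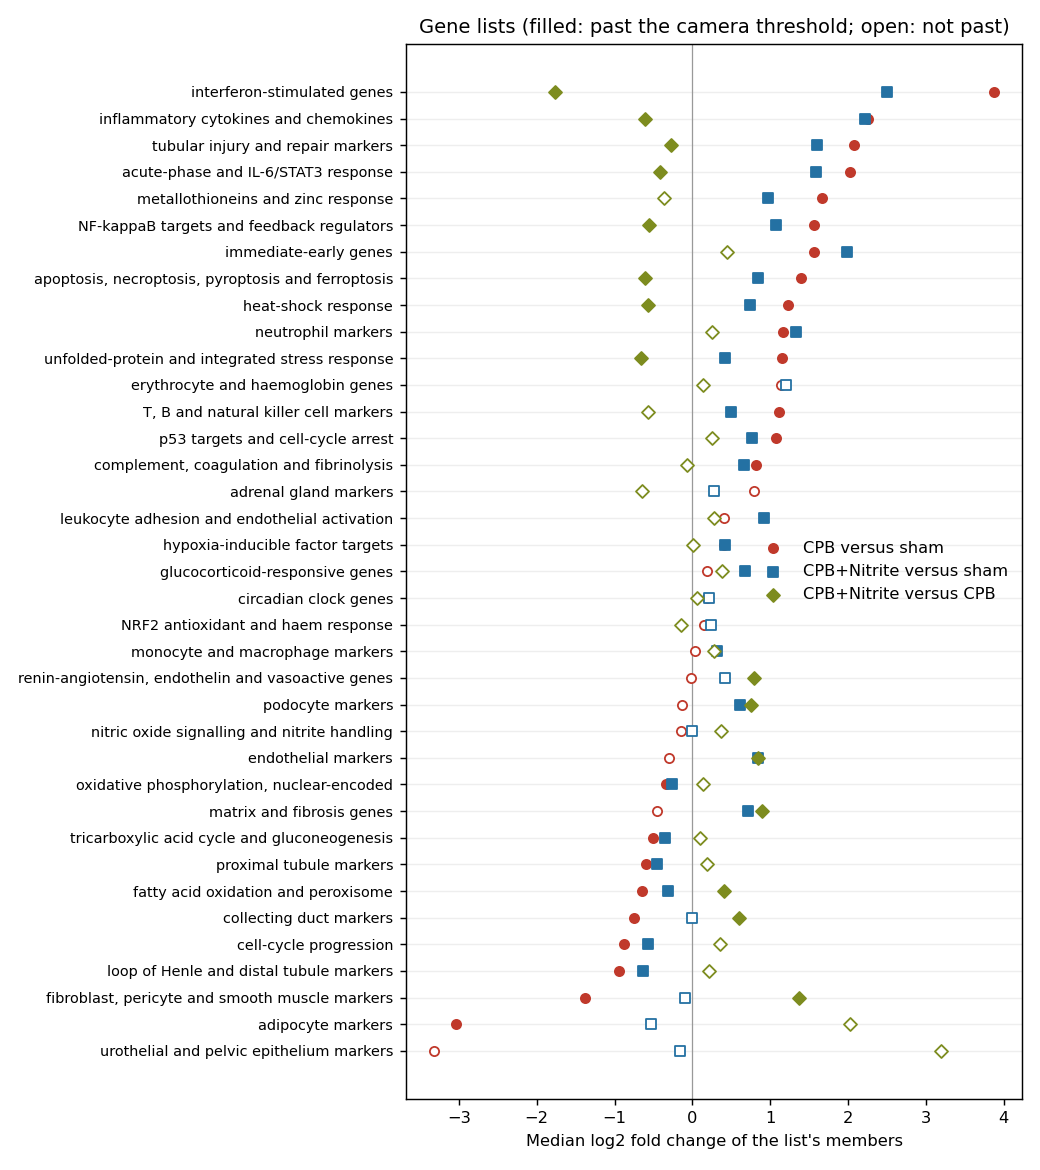
Median log2 fold change of the members of each of 37 gene lists in the 3 comparisons, with filled symbols for lists past the camera threshold with its preset correlation and open symbols for the others. Interferon-stimulated genes lie at 3.88 in CPB versus sham, 2.50 in CPB+Nitrite versus sham and -1.77 in CPB+Nitrite versus CPB.

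CPB+Nitrite versus sham addressed what remained different from control with nitrite. Part of the inflammatory, immediate-early and interferon-stimulated genes were higher than in sham. Hmox1 was at 8.42 ± 2.45 CPM in sham and 369 ± 344 in CPB+Nitrite (log2 change 5.45, standard error 0.78, adjusted p = 0.0145). Il6 rose by 5.15 and Cxcl2 by 5.18, while the anion transporter Slc22a6 (ENSRNOG00000018215, chromosome 1, 205522729 to 205531173) fell by 0.63 with a standard error of 0.16 (adjusted p = 0.0477). edgeR called 705 of 14664 genes (4.81%), 565 higher and 140 lower. In a fit of only the 8 libraries compared it called 0, so the calls given here depend on including the CPB libraries in the fit.

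Of 26 immediate-early genes 13 rose (24 adjusted over the list alone; median 1.98, camera adjusted p = 6.4e-14, adjusted p = 0.204 with an estimated correlation), including Fosb by 5.93, the nuclear receptor Nr4a1 by 2.69, Ier2 by 1.90 and Jund (ENSRNOG00000019568, chromosome 16, 18734122 to 18735799) by 1.46 with a standard error of 0.24. Of 25 interferon-stimulated genes 14 rose (25 adjusted over the list alone; median 2.50, camera adjusted p = 1.9e-12, adjusted p = 0.241 with an estimated correlation), Ifit3 by 4.07, Ifit2 by 3.42 and Irf7 by 2.91. Of 25 injury markers 11 rose (19 adjusted over the list alone; camera adjusted p = 3.69e-09, adjusted p = 0.204 with an estimated correlation), Havcr1 by 4.62, Timp1 by 3.32 and the keratin Krt18 by 1.96. Lcn2 was at 2.51 ± 3.92 CPM in sham and 14.6 ± 9.31 in CPB+Nitrite (adjusted p = 0.0869, and 0.0106 without sham 3). Of 25 cytokines and chemokines 11 rose (19 adjusted over the list alone; camera adjusted p = 5.45e-09, adjusted p = 0.241 with an estimated correlation), Ccl2 by 4.03 and Cxcl1 by 4.11. Il1b (log2 change 1.30, adjusted p = 0.0661) and Tnf (2.22, adjusted p = 0.092) did not pass. Fgg of the injury list rose by 5.71, at 205 CPM in CPB+Nitrite 1 and 3.99, 4.41 and 10.4 in CPB+Nitrite 2 to 4, and without CPB+Nitrite 1 the log2 change was 2.54 and the call was lost (adjusted p = 0.062). Of 18 acute-phase genes 7 rose (17 adjusted over the list alone; camera adjusted p = 3.68e-10, adjusted p = 0.204 with an estimated correlation), Cp by 1.39. Of 21 NF-kappaB targets 9 rose (14 adjusted over the list alone; camera adjusted p = 3.99e-07, adjusted p = 0.241 with an estimated correlation), Icam1 by 1.75. Of 20 p53 targets 5 rose (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.29e-05, adjusted p = 0.204 with an estimated correlation), the cell-cycle inhibitor Cdkn1a by 2.04 and the growth-arrest gene Gadd45b by 2.91.

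Nitric oxide genes past the threshold numbered 5 of 28, all higher (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.388). They included Nos3 by 1.53 with a standard error of 0.27 (adjusted p = 0.0262), Nos2 by 3.10 and Vasp, a substrate of the cyclic GMP pathway, by 1.13. For Nos3 more endothelium in the samples was not separated from a change in the gene itself, since all 20 endothelial markers had a positive log2 change. Of 20 endothelial markers 3 rose (9 adjusted over the list alone; camera adjusted p = 0.000125, adjusted p = 0.412 with an estimated correlation), Cdh5 by 1.73 and Robo4 by 1.29, and the median of that list, 0.84, was 0.32 without CPB+Nitrite 2. Of 14 neutrophil markers 3 rose (7 adjusted over the list alone; camera adjusted p = 4.19e-05, adjusted p = 0.0614 with an estimated correlation), S100a9 by 1.86. Complement and coagulation genes rose in 6 of 24, among them the plasminogen activator Plat by 1.95 (8 adjusted over the list alone; camera adjusted p = 0.000595, adjusted p = 0.123 with an estimated correlation). Cell-death genes rose in 7 of 26 (15 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.76e-05, adjusted p = 0.249 with an estimated correlation). Unfolded-protein genes rose in 4 of 24, Ppp1r15a by 3.58 (7 adjusted over the list alone; camera adjusted p = 0.00184, adjusted p = 0.457 with an estimated correlation). Hypoxia targets rose in 3 of 23 (9 adjusted over the list alone; camera adjusted p = 0.000186, adjusted p = 0.226 with an estimated correlation). Of 16 glucocorticoid-responsive genes 2 rose (7 adjusted over the list alone; camera adjusted p = 0.000761, adjusted p = 0.123 with an estimated correlation), Map3k6 by 1.89. Leukocyte adhesion, matrix, podocyte, macrophage and lymphoid lists, metallothioneins and heat-shock genes also passed camera as higher (adjusted p from 0.000497 to 0.0403, and adjusted p = 0.204 to 0.631 with an estimated correlation), with 0 to 2 members past the threshold in each and 0 to 5 adjusted over the list alone. Single libraries carried several of these shifts. Without CPB+Nitrite 2 the matrix median went from 0.72 to 0.01 and the adhesion median from 0.92 to 0.59, and without CPB+Nitrite 4 the heat-shock median went from 0.74 to 0.04 and the hypoxia median from 0.42 to 0.28. Without CPB+Nitrite 1 the medians of metallothioneins (0.98), complement and coagulation (0.66), unfolded-protein (0.43) and cytokine genes (2.22) were 0.42, 0.37, 0.23 and 1.48. The macrophage median (0.32) was 0.10, 0.52 and 0.20 without sham 3, sham 4 and CPB+Nitrite 1, and the lymphoid median (0.49) was 0.81 without sham 4.

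The lists that stood lower than sham had few genes past the threshold. Proximal tubule markers fell in 2 of 27 (6 adjusted over the list alone; camera adjusted p = 7.52e-05, adjusted p = 0.123 with an estimated correlation), Slc22a6 and the amino acid transporter Slc7a13, which fell by 1.04. Slc34a1 had a log2 change of -0.61 (adjusted p = 0.0681). Cell-cycle genes fell in 2 of 25 (7 adjusted over the list alone; camera adjusted p = 0.000333, adjusted p = 0.241 with an estimated correlation), Mki67 by 1.16 and Cenpf by 1.52. Loop and distal tubule markers fell in 1 of 21, the kinase gene Wnk1 by 1.24 (3 adjusted over the list alone; camera adjusted p = 0.000735, adjusted p = 0.241 with an estimated correlation). The median of that list, -0.64, was -0.36 without CPB+Nitrite 2. Umod had a log2 change of -0.68 (adjusted p = 0.46). Oxidative phosphorylation genes fell in 1 of 27, Ndufs1 by 0.66 (1 adjusted over the list alone; camera adjusted p = 0.000774, adjusted p = 0.5 with an estimated correlation; median -0.27, and -0.17 without CPB+Nitrite 4). The lists of fatty acid oxidation (camera adjusted p = 9.31e-05, adjusted p = 0.287 with an estimated correlation) and of the citric acid cycle (camera adjusted p = 1.49e-05, adjusted p = 0.226 with an estimated correlation) stood lower with 0 genes past the threshold by edgeR, at medians of -0.31 (-0.20 without sham 1) and -0.35 and with 0 and 4 genes adjusted over the list alone. Outside the lists, the transcription factor Stat5a fell by 1.75, the glucose transporter Slc2a4 by 1.83, the potassium channel Kcnj10 by 1.93 and Rimbp2 by 1.57, where Kcnj10 fell by 3.02 without CPB+Nitrite 3. The other 10 lists did not pass camera, among them antioxidant genes (0.291), collecting duct markers (0.5) and markers of fibroblasts, pericytes and smooth muscle (0.669).

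In this comparison 27 of 37 lists passed camera, 21 higher and 6 lower, while 0 passed with an estimated correlation and 20 passed fry. The count of 705 genes rested on single libraries: it was 3, 0, 427 and 1 without sham 1 to 4, 273, 98, 180 and 214 without CPB 1 to 4, and 71, 1796, 2976 and 0 without CPB+Nitrite 1 to 4, and the 120 list members past the threshold became 0 to 271. Genes without overlap between the groups numbered 1688 (11.5%), where chance gives 2.86% on average over all arrangements. This excess is untested too, since the share was not computed for the other arrangements.

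**Figure D4:**
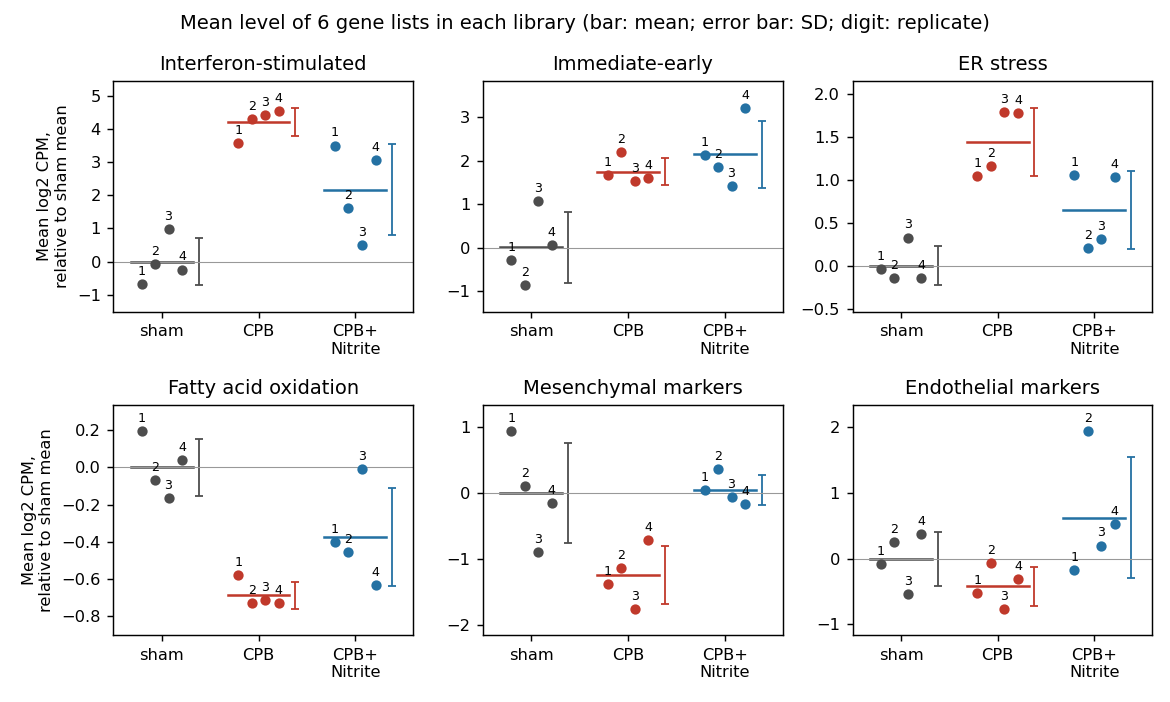
Mean log2 CPM of the members of 6 gene lists in each library, relative to the sham mean, with the mean (bar) and SD (error bar) of each group of 4 and the replicate number at each point. Interferon-stimulated genes lie at 3.57 to 4.53 in CPB and 0.50 to 3.5 in CPB+Nitrite, and immediate-early genes at 1.54 to 2.20 and 1.41 to 3.22.

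How far the bypass change remained with nitrite was taken from genes called on 2 sham and 2 CPB libraries and measured on the other libraries. Over 36 such splits, which called 1665 to 6971 genes, a median of 0.504 of the log2 change from sham to CPB was present in CPB+Nitrite (range over the splits 0.416 to 0.573). It was 0.489 for genes higher after bypass and 0.523 for genes lower. The single libraries lay far apart, with 0.849, 0.141, 0.199 and 0.763 for CPB+Nitrite 1 to 4 (SD 0.37, n = 4). A second calculation, with the sham mean at 0 and the CPB mean at 1, placed each library on genes called without it. Libraries of the sham group lay at -0.07 to 0.19, those of CPB at 0.754 to 1.09 and CPB+Nitrite 1 to 4 at 0.811, 0.128, 0.209 and 0.754. CPB+Nitrite 1 and 4 thus lay within the range of CPB. The quartiles over genes were -0.361 and 0.631 in CPB+Nitrite 2, against 0.0287 and 0.404 in CPB+Nitrite 3. CPB+Nitrite 2 thus scattered widely around its low median. It correlated with the sham mean at 0.926, close to CPB+Nitrite 1 (0.925) and 4 (0.927), against 0.982 for CPB+Nitrite 3. Of the 705 genes of CPB+Nitrite versus sham, 640 were also called in CPB versus sham in the same direction (504 higher, 136 lower). Both comparisons use the same sham libraries, so this overlap has no simple chance value. With the sham libraries split 2 and 2 between the comparisons it was 0, where CPB+Nitrite versus sham called 0 genes by edgeR in each of the 6 splits. Genes called in CPB versus sham and in the opposite direction in CPB+Nitrite versus CPB numbered 0 by edgeR and 1761 by DESeq2, and these comparisons share the CPB libraries with opposite sign.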

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

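In this part the tests on CPB+Nitrite 2 were chosen only after the result was seen, while those on CPB+Nitrite 1 were set down before they were run. A library far from the other 3 of its group, by the ratio of its gap to the group's whole range, was found in 17 of 390 groups of 4 values checked (list levels, depth, position between sham and CPB, and log2 CPM of the genes followed). Chance gives about 1 in 20 groups. Of the 17, 7 were in CPB+Nitrite 3. Over all tested genes that library correlated at 0.982 with the sham mean, within the range of the sham libraries (0.977 to 0.987). With the mean of the other libraries of its group it correlated at 0.96. Between sham (0) and CPB (1) it lay at 0.209, beside sham 3 at 0.185. Without it the share of the bypass change remaining was 0.6 instead of 0.504. Why it lay close to sham, by its label or its response, was not tested.

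CPB+Nitrite 3 was low for Irf7 (ratio 0.896; 5.44 log2 CPM against 7.92 to 8.21 in the other libraries of its group), Cxcl2 (0.894; 0.93 against 3.48 to 3.78), Icam1 (0.929; 5.27 against 7.28 to 7.44), Cfb (0.883; 4.69 against 7.05 to 7.37) and Map3k6 (0.954; 4.15 against 5.05 to 5.09). It was high for Slc7a13 (0.899; 10.6 against 9.41 to 9.53) and Wnk1 (0.853; 8.20 against 6.80 to 7). CPB+Nitrite 1 was high for Cp (0.843; 7.2 against 6.42 to 6.54), and CPB+Nitrite 4 was low for Top2a (0.871; -0.03 against 1.35 to 1.55). CPB 4 was high for Nfkb1 (0.850; 8.27 against 7.73 to 7.81) and Notch3 (0.925; 2.64 against 1.98 to 2.03). CPB 1 was high for the level of the fatty acid oxidation list (0.875; -0.58 against -0.73 to -0.71 relative to sham). Sham 1 was high for Acta2 (0.829; 6.88 against 3.90 to 4.41), sham 3 for the antioxidant list (0.839; 0.19 against -0.08 to -0.04), and sham 4 for Gldc (0.896; 6.40 against 5.77 to 5.84) and for the nitric oxide list (0.936; 0.18 against -0.07 to -0.05).

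CPB+Nitrite 2 was high for the level of erythrocyte and haemoglobin genes (0.885; 2.23 against -0.96 to -0.59 relative to sham), with Hba-a1 at 4150 CPM against 170 to 206 in the other 3 libraries. All 4 tested members of that list were at 1 CPM or more in sham. The same library stood apart in markers of several cell types: the median deviation from the other 3 was 1.36 for endothelial markers, with Plvap at 1380 CPM against 17.2 to 69.0, 0.364 for mesenchymal markers, 1.58 for adipocyte markers (9 of 12 higher) and -0.766 for loop and distal tubule markers. A lower share of tubule cells in the piece of kidney would raise the markers of other cell types alike, but the endothelial and mesenchymal medians differed by 0.996 (standard error over genes 0.35). These were the highest and lowest of the podocyte, endothelial and mesenchymal lists. More inner medulla would lower podocyte markers, whose median deviation was 0.956 (standard error over genes 0.13). Both values went against the predictions, but their errors treat the genes of 1 library as independent. They cannot show a difference beyond chance, so neither explanation is excluded. A difference in sequencing depth was argued against, since its 25.4 M reads lay within the range of the other 11 libraries. Blood, endothelium and fat in the piece sampled could contribute and stay open, and no biological explanation was tested for a single library.

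CPB+Nitrite versus CPB gave 0 genes by edgeR with CPB+Nitrite 1 included and 2836 without it, while 4315 genes had an unadjusted p under 0.05 with it and DESeq2 called 2235. One candidate explanation is that CPB+Nitrite replicate 1 is a mislabelled CPB library. On genes called between the other CPB+Nitrite libraries and 3 CPB libraries, its position, with CPB at 0 and those CPB+Nitrite libraries at 1, had a median of 0.273 (0.227 to 0.364 over the 4 choices of CPB libraries). The CPB library left out of each choice lay at -0.046 to 0.285, so this explanation remains open, although in each of the 4 choices CPB+Nitrite 1 lay above the CPB library left out. Urothelium and fat in CPB+Nitrite replicate 1 stays open too: the urothelial list was 2.31 log2 units above the sham mean there, with Upk1a at 52.2 CPM (63.2 in sham 1). The adipocyte list was at -0.102 in that library, against 0.572, -1.53 and -1.46 in CPB+Nitrite 2 to 4. With the levels of both lists as covariates edgeR called 0 genes (2889 with an unadjusted p under 0.05), which had been set down as evidence against it, but the covariates also lowered CPB versus sham from 6332 genes to 1359, so that count decides nothing. All 10 urothelial and all 12 adipocyte markers tested had a mean of 1 CPM or more over the sham libraries, and 2 of the adipocyte markers are in another list. Sham 1 carried part of these means. Upk3a was at 31.2, 5.23, 0.736 and 0 CPM in sham 1 to 4, and Cfd at 59, 14.1, 0.45 and 0.338. An animal that responded less to nitrite stays open as untested.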

How the results depend on the processing

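In this part the deposited table's scaling, the threshold of 0.1 and the leaving out of third-group libraries were chosen only after the result was seen. In CPB versus sham the counts of all genes past the threshold, higher and lower, stayed within 1.5 times their values under every alternative named in the processing part. The covariate fit, not among those alternatives, lowered the count from 6332 to 1359. Counts within single lists moved further with a library left out (oxidative phosphorylation from 8 to 2 without CPB 2). Of 56 called genes among those followed at most 3 lost their call under any named alternative (2 under voom, 3 without CPB 2). Lists past the threshold numbered 24, 15 and 27 in the 3 comparisons, 0 in each with an estimated correlation, and 25, 1 and 20 by fry, and the cause was not tested. The share of the bypass change remaining, 0.504, was 0.391, 0.604, 0.6 and 0.404 without CPB+Nitrite 1 to 4, 0.501 with RLE and 0.489 when called and measured on all libraries.

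The 0 genes of CPB+Nitrite versus CPB became 2235 by DESeq2 (1347 higher, 888 lower), 1 by voom (1 higher) and 2391 at a threshold of 0.1 (1491 higher, 900 lower), and 0 to 2836 with a library left out (0 to 1661 higher, 0 to 1175 lower). The 2836 came without CPB+Nitrite 1, and 4 genes passed without CPB 1. The 705 of CPB+Nitrite versus sham (565 higher, 140 lower) became 28 (27, 1) with the replicate block, 2144 (1434, 710) by DESeq2, 2870 (1599, 1271) by voom, 139 (131, 8) by glmTreat, which asks for more than 1.2-fold, 0 (0, 0) on only the 8 libraries and 2128 (1389, 739) at a threshold of 0.1. It was 0 to 2976 with a library left out (0 to 1620 higher, 0 to 1356 lower), as given for each library in the report, and all 42 called genes followed there lost their call without sham 2, sham 4 or CPB+Nitrite 4. Outside the threshold, the cause of these differences was not tested. Replicate numbers shared between groups gave little sign of pairing: their deviations correlated above 0.1 in 3 of 12 cases and a sample's own number gave the best match in 3 of 12.

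Genes near 0 changed sign. Nos3 in CPB versus sham (0.02) was at -0.159 by total counts, -0.0178 with the stricter filter, -0.00522 with the replicate block and -0.109 to 0.172 with a library left out. Il1b in CPB+Nitrite versus CPB (0.01) was at -0.00407 with RLE, -0.00322 without a filter, -0.097 with the block, -0.00728 by DESeq2, -0.0161 by voom and -0.504 to 0.277 with a library left out. Cxcl1 there (-0.25) was at -1.06 by voom and at -0.841 to 0.127 with a library left out, positive without CPB+Nitrite 3. The cause was not tested. At these depths and 4 replicates, changes of 1.5-fold were recovered in 2.99% to 4.48% of simulated genes, so genes that did not pass are not shown to be unchanged.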

Other observations

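In this part the enrichment of biological process terms, the comparison of interferon with immediate-early genes and the splits for genes in both CPB+Nitrite comparisons were chosen only after the result was seen. Beyond the lists, 92 of 976 terms were enriched among genes higher in CPB versus sham and 16 among genes lower (one-sided hypergeometric test, Benjamini-Hochberg adjusted p under 0.05, genes not being independent). Among these were genes of ribosome production, with 29 of 55 genes of rRNA processing higher (12.4 expected, adjusted p = 8.31e-05) and 24 of 41 of small ribosomal subunit biogenesis (9.28 expected, adjusted p = 6.59e-05). Protein import into the nucleus had 31 of 59 genes higher (13.4 expected, adjusted p = 5.01e-05) and protein ubiquitination 66 of 179 (40.5 expected, adjusted p = 0.000459). Among lower genes, transmembrane transport held 147 of 338 (71.5 expected, adjusted p = 4.78e-18) and cilium assembly 56 of 136 (28.8 expected, adjusted p = 4.06e-05). Glycogen metabolic process (11 of 16, 3.38 expected, adjusted p = 0.00773) and calcium ion transmembrane transport (24 of 55, 11.6 expected, adjusted p = 0.0154) were also enriched among lower genes.

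In CPB+Nitrite versus sham 38 terms were enriched among higher genes and 1 among lower genes. These rest on the 705 genes called there, a count that was 0 on only the 8 libraries and 3, 0, 1 and 0 without sham 1, sham 2, sham 4 and CPB+Nitrite 4. The cellular response to lipopolysaccharide held 19 of 75 genes (3.08 expected, adjusted p = 1.05e-07), positive regulation of the ERK1 and ERK2 cascade 20 of 97 (3.99 expected, adjusted p = 8.79e-07), chemotaxis 10 of 36 (1.48 expected, adjusted p = 0.000236) and positive regulation of angiogenesis 11 of 85 (3.49 expected, adjusted p = 0.0223). The lower term was transmembrane transport, with 17 of 338 (3.21 expected, adjusted p = 1.6e-05). In CPB+Nitrite 2 the zinc transporter gene Slc39a7, chosen after its values were seen, had 0 reads, against 28.7 to 66.8 CPM in the other 11 libraries, and no other tested gene at 1 CPM or more in 11 libraries had 0 reads in the remaining one.

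Interferon-stimulated genes lay lower in CPB+Nitrite than in CPB while immediate-early genes did not. With the sham mean at 0 and the CPB mean at 1, the interferon list lay at 1 ± 0.104 in CPB and 0.516 ± 0.326 in CPB+Nitrite (SD, n = 4, exact permutation p = 0.0286), and the immediate-early list at 1 ± 0.175 and 1.23 ± 0.443 (exact permutation p = 0.429). The difference between the lists was 0 ± 0.201 in CPB and -0.716 ± 0.304 in CPB+Nitrite (exact two-sided permutation p = 0.0286, the smallest that 70 arrangements can give). That p is not adjusted for the choice of these lists, which were picked because they were seen to move apart, so an equal fall of both responses toward sham stays open. Over the 24 lists that passed in CPB versus sham the adjusted exact p of the interferon position was 0.229. Since no exact p can fall below 0.0286, a list could pass this adjustment only if many lists reached that minimum. The adjusted value therefore decides nothing.

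Splits of the 8 libraries of each comparison into other groups of 4 bear on whether labels matter. For genes, 1 of 35 splits, the real one, gave as many as 6332 in CPB versus sham (highest other 0). In CPB+Nitrite versus sham 1 of 35, again the real one, gave as many as 705 (highest other 116). A share of 1 in 35 is the smallest these splits can give, and it was not adjusted for the other counts tested. It argues against chance in both without excluding it. The count of 705 was also not stable: it was 28 with the replicate numbers as a block, 0 on only these 8 libraries, and 3, 0, 1 and 0 without sham 1, sham 2, sham 4 and CPB+Nitrite 4. In CPB+Nitrite versus CPB the real count by edgeR was 0 (4315 genes had an unadjusted p under 0.05, DESeq2 called 2235 and voom 1), which any split reaches, 35 of 35, so the splits say nothing about chance there. The highest other split, which exchanged CPB+Nitrite 4 for CPB 1, gave 25. By genes with an unadjusted p under 0.05 the real split gave 4315 and the others up to 3908, in the split that set CPB+Nitrite 1 with CPB 2, CPB 3 and CPB 4. For gene lists chance is not excluded in any of the 3 comparisons: 3 of 35 splits gave as many as 24 in CPB versus sham (highest other 25), 7 of 35 as many as 15 in CPB+Nitrite versus CPB (highest other 22), and 2 of 35 as many as 27 in CPB+Nitrite versus sham (highest other 27). In both comparisons with sham, the other splits that matched kept 3 libraries of a group together. Such splits keep part of the difference between the groups, so they do not measure chance alone. Splits that mixed the groups 2 and 2 gave up to 15 lists in CPB versus sham and 18 in CPB+Nitrite versus sham. In CPB+Nitrite versus CPB they gave up to 20.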
